A study of Homo sapiens with 16 samples.

How the data were processed

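H3K27ac, H3K9ac and SMAD3 were profiled by ChIP-seq in H69 cells treated with vehicle or with TGF-beta at 10 ng/ml for 16 h. Each target had 2 vehicle and 2 TGF-beta libraries, numbered 1 and 2 for the acetylation marks and 4 and 5 for SMAD3. Per the labels' protocols, chromatin was crosslinked for 10 min in 1% formaldehyde, and 51-base paired-end reads were sequenced. Per the submitters' processing notes, the tools were BWA, Picard, MACS2 and bedtools and the genome build was hg38; versions, the order of steps, the cutoff of the peak caller and the input used as control are not given in the sources used here. The authors deposited 1 peak file per library, whose score column holds -log10 of the caller's p or q value (neg_log10_p); which of them was used is not given in the sources used here. The smallest score was 2.00 to 2.04 across the 12 files. The median score differed between treatments. It was 12.2 and 12.8 with vehicle and 14.3 and 14.3 with TGF-beta in H3K27ac. In H3K9ac it was 15.9 and 17.3 with vehicle and 21.4 and 21.3 with TGF-beta. In SMAD3 it was 26.9 and 24.6 with vehicle and 15.0 and 13.8 with TGF-beta. Scores were used only to rank peaks within a library. Per the file headers, the TGF-beta replicate 2 libraries of H3K27ac and H3K9ac were sequenced on lane 8 and the other libraries of these marks on lane 7, while every SMAD3 library was on lane 8. The 4 input samples were not used here.

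Peaks on chromosomes 1 to 22 and X were used, which left out 7 to 66 peaks per library on other sequences. Median peak length was 378 to 441 bp. The files hold no read counts, so read depth is unknown and no counting error can be given; the length called is limited by depth in a way that cannot be removed here. Peaks of the 4 libraries of a target were merged where they overlapped by at least 1 bp, and each merged region was scored as called or not in each library. Regions called in both libraries of a treatment and in neither of the other were taken as gained (TGF-beta) or lost (vehicle), and those called in all 4 as constant. Regions were assigned to the nearest protein-coding gene within 50 kb, and a region within 1 kb of either end of a gene was taken to lie at a gene end.

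Genes were the 19974 protein-coding genes of the RefSeq annotation of GRCh38. The value of a gene was the length inside peaks in its span with 10 kb on each side. A window around the start site had been planned; the annotation used gives no strand and no exons, so both ends of a gene were treated alike and the gene span was used in its place, and exon or intron is not given for any region. Windows of neighbouring genes overlap, so main counts of genes are also given as separate loci, and tests on genes take neighbours as independent. Values were analysed as log2 of the length plus 500 bp in genes with a mean of at least 500 bp, after centring each library on the median over genes covered in all 4 libraries. Log2 changes are TGF-beta minus vehicle. Treatment was tested with limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05, and whether the change differed between the marks was tested as a treatment by mark term. With 2 libraries against 2, limma borrows the spread of other genes, and an exact permutation test of a single gene cannot go below 0.333. Region classes were compared with two-sided Fisher's exact tests, which treat regions as independent and so measure no spread between libraries. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

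The 17 gene lists held 391 entries, all matched to the annotation. They covered TGF-beta and SMAD targets, BMP and ID targets, matrix and collagen genes, integrin and cytoskeleton genes, the epithelial to mesenchymal transition, epithelial junctions, cholangiocyte identity, secreted profibrogenic factors, AP-1 and immediate early genes, YAP targets, the cell cycle, acetylation machinery, interferon response, markers of hepatocytes, of mesenchymal and endothelial cells and of leukocytes, and housekeeping genes. Lists were tested against other genes with camera (correlation of 0.01 preset, and an estimated correlation as the alternative), and by region with Fisher's exact test of gained against lost regions near members. With an estimated correlation, camera takes its degrees of freedom from the 4 libraries alone, so a list can hardly pass whatever its correlation. The lists, the comparisons, the tests, the rule for named genes and the other settings listed, except those named as added, were chosen before the data were examined. The rule named, per target, the 8 genes with the largest change in each direction past the threshold whose TGF-beta libraries both lay outside the range of the vehicle libraries, per list up to 4 members with the most gained and 2 with the most lost regions, the 5 genes with the largest difference between marks in each direction, and genes fixed by name such as TGFBI and KRT7. Other list members and genes named in the text, 30 of 151, were chosen after their values were seen. Genes of chromosome Y and XIST were left out, and some genes that the rule names are not reported here.

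The other settings tried were merging peaks within 500 bp, requiring peaks to cover 0.5 of a region, the better-scored 0.5 of each library's peaks, the same number of peaks from each library, windows of 2.5 and 50 kb, pseudocounts of 100 and 2000 bp, no filter, no centring, replicate number as a block, limma with trend and robust options, overlaps of 0.5 of the shorter region, region centres of 200 bp, and leaving out each library in turn. Settings added after seeing the data were windows of 10 kb around both gene ends, a block with replicate numbers crossed for H3K9ac, the treatment by mark test without each library in turn or without both lane 8 libraries, and the location of regions with the same number of peaks. The method was tested on simulated data: 200 genes per target were given known changes, in 20 random draws. The noise was normal and independent between genes and libraries, with the spread that limma estimated for each gene. Overlap of windows and effects of library, lane or depth were not simulated, so the test is easier than the real data. Over the draws, changes of 1.25, 1.5 and 2 fold were called for 10.3 to 39.7%, 90.9 to 100.0% and 100.0% of genes in H3K27ac, 23.5 to 42.6%, 93.9 to 100.0% and 100.0% in H3K9ac and 0 to 13.2%, 47.0 to 81.8% and 97.0 to 100.0% in SMAD3, with 4.90 to 17.2%, 5.00 to 13.5% and 3.80 to 15.9% of calls false. The classes of 3000 simulated regions were recovered with 0 mismatches.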

Results

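H69 is a virally transformed line of human cholangiocytes, the epithelial cells that line bile ducts. Cells were treated for 16 h with vehicle or with recombinant human TGF-beta at 10 ng/ml, a growth factor that drives fibrosis and signals through SMAD3. Chromatin immunoprecipitation with sequencing (ChIP-seq) was done for H3K27ac and H3K9ac, which are acetylation marks of active enhancers and promoters, and for SMAD3. Each of the 3 targets had 2 vehicle and 2 TGF-beta libraries, numbered 1 and 2 for the marks and 4 and 5 for SMAD3, and 4 input samples were not used here. Each of the 12 files listed the peaks of 1 library without read counts, so read depth is unknown and the length of genome inside peaks stands in for it. The labels do not say whether replicates were separate cultures, so p-values from limma measure only the spread between these libraries.

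SMAD3 peaks numbered 22451 and 25268 in vehicle replicates 4 and 5, and 33700 and 34413 in TGF-beta replicates 4 and 5. They covered 12.8 ± 2.33 Mb with vehicle and 19.6 ± 0.0395 Mb with TGF-beta (mean ± SD, n = 2 libraries). H3K27ac peaks numbered 82259 and 83429 in vehicle replicates 1 and 2 and 92714 and 90092 in TGF-beta replicates 1 and 2, and covered 56.9 ± 3.11 and 64.4 ± 0.965 Mb. H3K9ac peaks numbered 61297 and 55069 with vehicle and 54682 and 56825 with TGF-beta, and covered 41.7 ± 3.42 and 39.2 ± 3.53 Mb. The H3K9ac means differed by less than their spread, and with 2 libraries against 2 an exact two-sided permutation test of a single value cannot give a p below 0.333. Libraries of the same treatment shared more of their covered length than libraries of different treatments did. The shared fraction (Jaccard index) was 0.681 to 0.700 against 0.515 to 0.602 for SMAD3, 0.745 to 0.778 against 0.629 to 0.644 for H3K27ac, and 0.767 to 0.798 against 0.690 to 0.720 for H3K9ac.

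**Figure D1:**
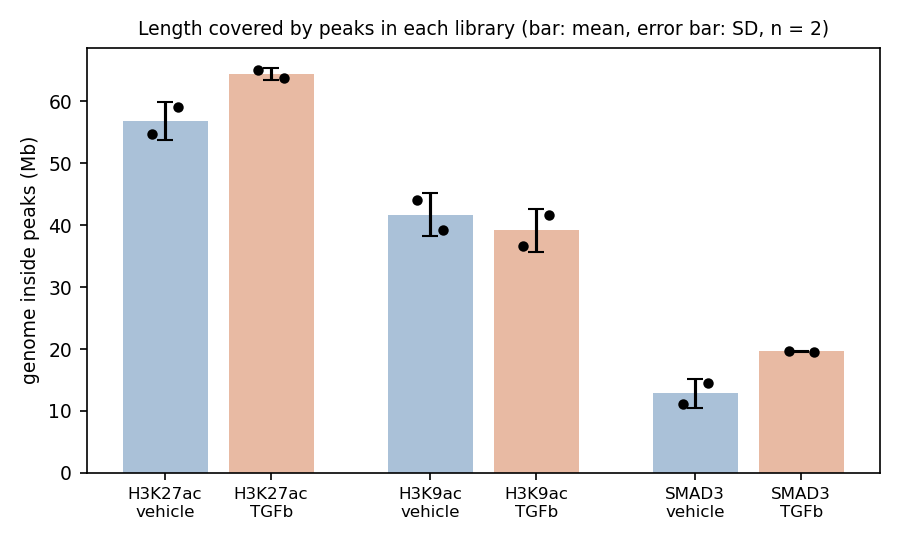
Length of the genome inside peaks (Mb, vertical axis) for each target and treatment, with bars for the mean of 2 libraries, error bars for the SD and points for libraries. SMAD3 means were 12.8 Mb with vehicle and 19.6 Mb with TGF-beta, while the H3K9ac means, 41.7 and 39.2 Mb, differed by less than their spread.

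The SMAD3 comparison asked where SMAD3 was found on chromatin after TGF-beta. TGFBI, which encodes a matrix protein named for its induction by TGF-beta (chromosome 5, 136028988 to 136063818, GRCh38), rose from 0.720 ± 0.274 to 33.8 ± 6.24 kb (log2 change 4.50 ± 0.165 SE, adjusted p = 1.54e-05), measured as peak length in the gene with 10 kb on each side (mean ± SD, n = 2 libraries per group). PMEPA1, a membrane protein that dampens TGF-beta signalling (chromosome 20, 57648396 to 57711472), rose from 1.40 ± 0.783 to 26.2 ± 3.46 kb (log2 change 3.55 ± 0.210 SE, adjusted p = 5.95e-05). ITGB6, the integrin subunit of a receptor that activates latent TGF-beta (chromosome 2, 160099671 to 160200272), rose from 0.507 ± 0.344 to 5.14 ± 0.457 kb (log2 change 2.20). MUC6, a secreted gel-forming mucin (chromosome 11, 1012823 to 1036718), fell from 3.66 ± 1.19 to 0.0805 ± 0.114 kb (log2 change -3.15 ± 0.173 SE, adjusted p = 4.78e-05).

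Across the genome, 5253 merged SMAD3 regions were called in both TGF-beta libraries and in neither vehicle library, and 257 the other way round, so 95.3% of the regions specific to a treatment were gains. A further 15998 regions were called in all 4 libraries. Pairs that mixed 1 library of each treatment gave 71 to 549 such regions. Gained regions had a median length of 365 bp against 939 bp for regions called in all 4 libraries, and 24.0% of them lay within 1 kb of an end of a protein-coding gene, against 72.0% of the constant regions (odds ratio 0.123, 95% interval 0.115 to 0.133, two-sided Fisher's exact test). Another 42.2% of gained regions lay within genes and 33.8% outside them. The 257 lost regions were also short, at a median of 269 bp, and 27.2% of them lay within 1 kb of a gene end. A position away from gene ends was therefore not particular to gained regions. With the same number of peaks taken from each library, 1691 regions were gained and 563 lost. In single pairs, regions gained per region lost were 15.7 and 20.5 with vehicle replicate 4 and 4.67 and 5.34 with vehicle replicate 5. With the same number of peaks these were 2.95 and 3.16, and 1.52 and 1.53. The vehicle libraries differed from each other by ratios of 6.98 and, with the same number of peaks, 2.90, and the TGF-beta libraries by 1.03 and 1.04. Median peak scores were 26.9 and 24.6 in vehicle replicates 4 and 5 and 15.0 and 13.8 in TGF-beta replicates 4 and 5. The libraries thus differed in the strength of their peaks as well as in number, and whether read depth gave this was not tested. The size of the excess is therefore uncertain. Leaving out a library loosens the definition: gained regions numbered 12572 and 12327 without TGF-beta replicates 4 and 5, and lost regions numbered 1627 and 546 without vehicle replicates 4 and 5 and 406 and 614 without TGF-beta replicates 4 and 5.

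**Figure D2:**
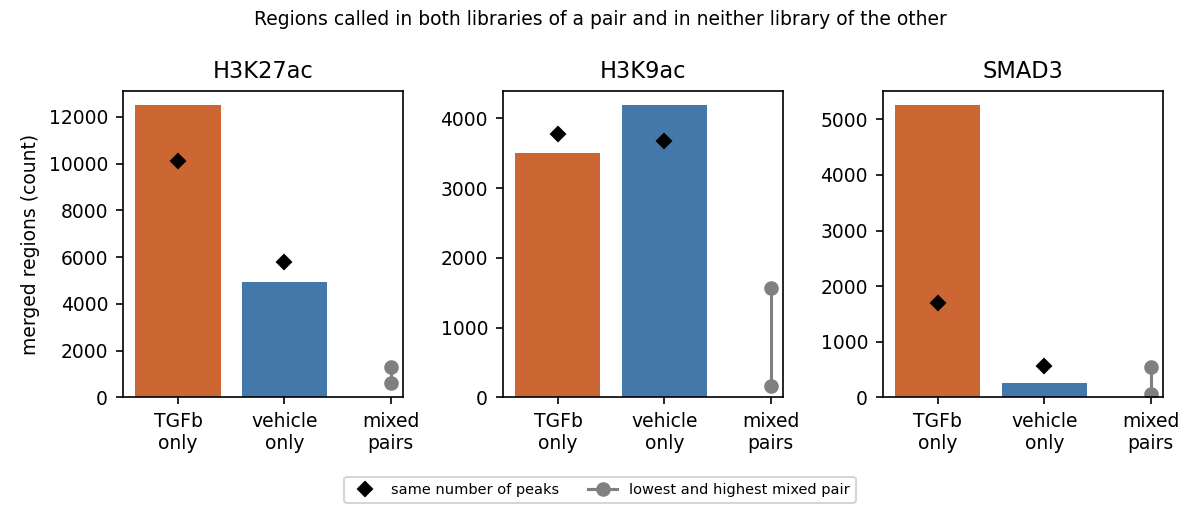
Number of merged regions (vertical axis, counts, scaled per panel) called in both libraries of 1 treatment and in neither library of the other, for each target. Bars give all peaks, diamonds the same number of peaks from each library, and grey points the lowest and highest pair that mixed the treatments: for SMAD3, 5253 regions were specific to TGF-beta and 257 to vehicle, and mixed pairs gave 71 to 549.

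By gene, 1395 of 12508 tested genes rose and 210 fell in SMAD3 (limma with Benjamini-Hochberg adjustment), in 872 and 176 separate loci. The genes with the largest gains included KCNA7 (log2 change 4.42), a potassium channel gene, and its neighbours on chromosome 19, NTF4 (3.85) and CGB7 (3.17), whose windows overlap. The gonadotropin paralogs there may make read placement uncertain, which peak lists do not show. TREH, which encodes trehalase, rose by 2.96 on the log2 scale. COMP, a cartilage matrix protein, and KIAA1755 were listed at 0 in both vehicle libraries and at 4.48 and 4.01 kb and 6.44 and 3.25 kb in the TGF-beta libraries. Among the largest losses were SECTM1 (-1.91), ACSS1 (-1.84), a mitochondrial acetyl-CoA synthetase, MLXIPL (-1.69), a glucose-responsive transcription factor, CITED2 (-1.62), a partner of the acetyltransferases CBP and p300, and GREB1 (-1.56). CD7, which shares its window with SECTM1, and LOC124902605, which shares its window with MUC6, were listed at 0 after TGF-beta and at 1.99 and 2.94 kb and 1.93 and 2.48 kb with vehicle.

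The library median of SMAD3 peak length, over genes covered in all 4 libraries, was 0.32 higher on the log2 scale after TGF-beta. Changes are given relative to this shift. Without centring, 1825 genes rose and 11 fell, so the share that rose was 99.4% in place of 86.9%. The losses of KRT19, CXCL2, BMP4, KAT2B, ITGB8 and EMC7 named with their lists kept their sign without centring, at -0.77, -0.26, -0.15, -0.29, -0.21 and -0.13, but did not pass (adjusted p from 0.212 to 0.474). The count of called genes was 712 (624 up, 88 down) with the same number of peaks per library, 3021 (2255 up, 766 down) with a window of 50 kb, and 789 (706 up, 83 down) without vehicle replicate 4.

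Of TGF-beta and SMAD target genes, 18 of 28 measured members rose, 0 fell and 10 did not pass in SMAD3. Adjusted over the list alone, 20 rose and 0 fell. TGFBI and PMEPA1 were joined by ANGPTL4 (2.41), SMAD7 (1.60), NEDD9 (1.41), RUNX1 (1.14) and SKIL (1.04). SMAD7 and SKIL encode inhibitors of SMAD signalling. CCN2, which encodes connective tissue growth factor, rose by 0.60, a call lost without vehicle replicate 4 or TGF-beta replicate 4 (adjusted p from 0.0692 to 0.154). Of extracellular matrix and collagen genes, 15 of 24 measured members rose, 0 fell and 9 did not pass, and adjusted over the list alone 16 rose and 1 fell. Examples were FN1 (2.14), fibronectin, COL1A1 (1.61), a chain of type I collagen, COL4A2 (1.60) and SPARC (1.60). Of integrin and cytoskeleton genes, 15 of 25 measured members rose, 1 fell and 9 did not pass, and adjusted over the list alone 15 rose and 2 fell. TAGLN (2.51), an actin-binding protein, ITGB6 (2.20), ITGA5 (1.48), ITGB1 (1.44) and PALLD (1.47) were among them. ITGB8 fell by 0.53, a call lost without vehicle replicate 4, vehicle replicate 5 or TGF-beta replicate 4 (adjusted p from 0.0648 to 0.175). With the same number of peaks per library, which lost the calls of 30 named genes in SMAD3 (adjusted p from 0.0554 to 0.825), those of CCN2, ITGA5, PALLD and ITGB8 were among them. The call of ITGB8 was also lost with a window of 2.5 kb, and both ITGB8 and CCN2 with a pseudocount of 100 bp.

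As sets, the TGF-beta targets (adjusted p = 4.50e-12), matrix genes (2.48e-09) and integrin and cytoskeleton genes (1.63e-06) lay above other genes in camera with a preset correlation. With an estimated correlation these calls were lost (adjusted p = 0.640, 0.516 and 0.640 in camera). The few degrees of freedom that 4 libraries leave there mean that the loss does not show an effect of correlation. The other 14 lists had adjusted p from 0.0914 to 0.971. By region, 96 gained and 0 lost SMAD3 regions lay near TGF-beta targets (exact p = 0.0144, adjusted p = 0.244, two-sided Fisher's test), and no list passed.

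The remaining lists moved in small numbers. Of secreted profibrogenic factors, 5 of 19 measured members rose, 1 fell and 13 did not pass (adjusted over the list alone, 7 rose and 1 fell), with IL11 (1.30), a profibrotic cytokine, LIF (1.07), PDGFA (0.96) and PDGFB (1.06), a growth factor subunit, among those that rose. CXCL2 fell by 0.58. For genes of the epithelial to mesenchymal transition, 4 of 14 measured members rose, 1 fell and 9 did not pass (adjusted over the list alone, 4 rose and 2 fell), including SNAI2 (1.22), which represses epithelial genes, and WNT5B (-1.01). Of BMP and ID targets, 3 of 12 measured members rose, 1 fell and 8 did not pass (adjusted over the list alone, 5 rose and 2 fell). NOG, an antagonist of BMP ligands (listed at 0 with vehicle, 1.20 and 1.36 kb with TGF-beta), SMAD6 (0.76) and ID2 (0.61) rose and BMP4 fell by 0.47. Among epithelial junction genes 3 of 20 measured members rose, 0 fell and 17 did not pass (adjusted over the list alone, 4 rose and 3 fell), namely JUP (0.93), CLDN7 (0.64) and CGN (0.51), with CGN at -0.10 in a window of 2.5 kb, while CDH1, which encodes E-cadherin, had a log2 change of -0.52 (adjusted p = 0.0529). Of cholangiocyte identity genes, 1 of 15 measured members rose, 1 fell and 13 did not pass (adjusted over the list alone, 1 rose and 1 fell). SLC4A2 (0.56), an anion exchanger of bile secretion, rose and KRT19, a keratin of bile ducts, fell by 1.10. KRT7, another duct keratin, had 20.4 ± 2.60 and 26.5 ± 0.206 kb (adjusted p = 0.787). For AP-1 and immediate early genes 3 of 19 measured members rose, 0 fell and 16 did not pass (adjusted over the list alone, 3 rose and 0 fell), MAFK (1.64), JUN (0.76) and IER3 (0.55), with IER3 at -0.067 in a window of 2.5 kb, and for YAP targets 4 of 21 measured members rose, 0 fell and 17 did not pass (adjusted over the list alone, 7 rose and 0 fell), NUAK2 (0.97), DLC1 (0.88), AMOTL1 (0.80) and FSTL1 (0.52). Few SMAD3 calls fell on lists of other functions. 1 of 24 measured cell cycle genes rose, 0 fell and 23 did not pass (adjusted over the list alone, 1 rose and 0 fell), the riser being CDKN2A (0.62), a cell cycle inhibitor. Of acetylation machinery genes 0 of 20 measured members rose, 1 fell and 19 did not pass (adjusted over the list alone, 0 rose and 1 fell). KAT2B, an acetyltransferase of H3K9, fell by 0.61. For interferon response genes, 1 of 18 measured members rose, 0 fell and 17 did not pass (adjusted over the list alone, 1 rose and 0 fell), with IFI27 (1.26). Markers of other cells were sparsely covered. For hepatocyte markers 0 of 2 measured members rose, 0 fell and 2 did not pass, with 0 at an unadjusted p under 0.05 in limma and 0 rose and 0 fell adjusted over the list alone. For mesenchymal and endothelial markers 2 of 5 measured members rose, 0 fell and 3 did not pass (adjusted over the list alone, 2 rose and 0 fell), PDGFRB (1.15) and THY1 (0.69), and for leukocyte markers 1 of 7 measured members rose, 0 fell and 6 did not pass (adjusted over the list alone, 1 rose and 2 fell), CD4 (1.32). Among housekeeping genes 1 of 20 measured members rose, 1 fell and 18 did not pass (adjusted over the list alone, 1 rose and 0 fell), HSP90AB1 (0.86) and EMC7 (-0.45). Without vehicle replicate 4 the calls of PDGFB, ID2, CLDN7, IER3, JUN, DLC1 and AMOTL1 were lost (adjusted p from 0.0585 to 0.215), without vehicle replicate 5 those of KRT19 and CXCL2 (adjusted p from 0.0707 to 0.154), and without either replicate 4 library those of SLC4A2, CDKN2A and KAT2B (adjusted p from 0.0615 to 0.140). The calls of BMP4 and EMC7 were lost when any 1 of the 4 libraries was left out (adjusted p from 0.0577 to 0.191), that of FSTL1 without vehicle replicates 4 and 5 and TGF-beta replicate 5, and that of CGN without all but TGF-beta replicate 5 (adjusted p from 0.0920 to 0.171). The calls of IL11, PDGFB, CXCL2, SMAD6, ID2, BMP4, JUP, CGN, SLC4A2, KRT19, JUN, NUAK2, DLC1, CDKN2A, KAT2B, IFI27 and EMC7 were lost with the same number of peaks per library. Windows of 2.5 kb lost those of PDGFB, BMP4, CLDN7, KRT19, NUAK2, DLC1, CDKN2A, HSP90AB1 and EMC7, windows of 50 kb those of KRT19, FSTL1 and THY1, and windows around gene ends those of JUP, KRT19 and EMC7. A pseudocount of 100 bp lost those of BMP4, CGN, SLC4A2, KRT19, JUN, IER3, DLC1, AMOTL1, CDKN2A, IFI27 and EMC7, and a pseudocount of 2000 bp those of KRT19, DLC1, AMOTL1, FSTL1 and EMC7. Limma with trend and robust options lost those of BMP4, DLC1, KRT19 and SLC4A2, and replicate number as a block that of EMC7. No filter lost those of BMP4, DLC1, KRT19 and EMC7, and no centring also that of DLC1. List medians, means and tests differed in sign for junction genes and cell cycle genes (test and median below 0, means 0.00 and 0.01), for acetylation machinery and interferon genes (tests below 0, medians and means above), and for leukocyte markers (test below 0, median 0.00).

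The H3K27ac comparison asked which enhancers and promoters changed their acetylation. COL1A1 (chromosome 17, 50184101 to 50201631) rose from 9.37 ± 0.822 to 22.6 ± 0.354 kb (log2 change 1.14 ± 0.0789 SE, adjusted p = 0.000232), and FN1 (chromosome 2, 215360865 to 215436068) rose from 3.77 ± 0.291 to 7.76 ± 0.0403 kb (log2 change 0.87). TNS1, a focal adhesion protein (chromosome 2, 217799791 to 218033982), rose from 0.566 ± 0.200 to 11.6 ± 0.574 kb (log2 change 3.43 ± 0.150 SE, adjusted p = 6.06e-05). CDH1 (chromosome 16, 68737292 to 68835537) fell from 28.6 ± 2.09 to 19.9 ± 0.541 kb (log2 change -0.60 ± 0.0749 SE, adjusted p = 0.00198), and KRT19 (chromosome 17, 41523617 to 41528308) fell from 7.89 ± 0.218 to 5.72 ± 0.928 kb (log2 change -0.53). APOB, an apolipoprotein made by hepatocytes (chromosome 2, 21001429 to 21044073), fell from 5.33 ± 0.103 to 0.694 ± 0.00636 kb (log2 change -2.38).

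**Figure D3:**
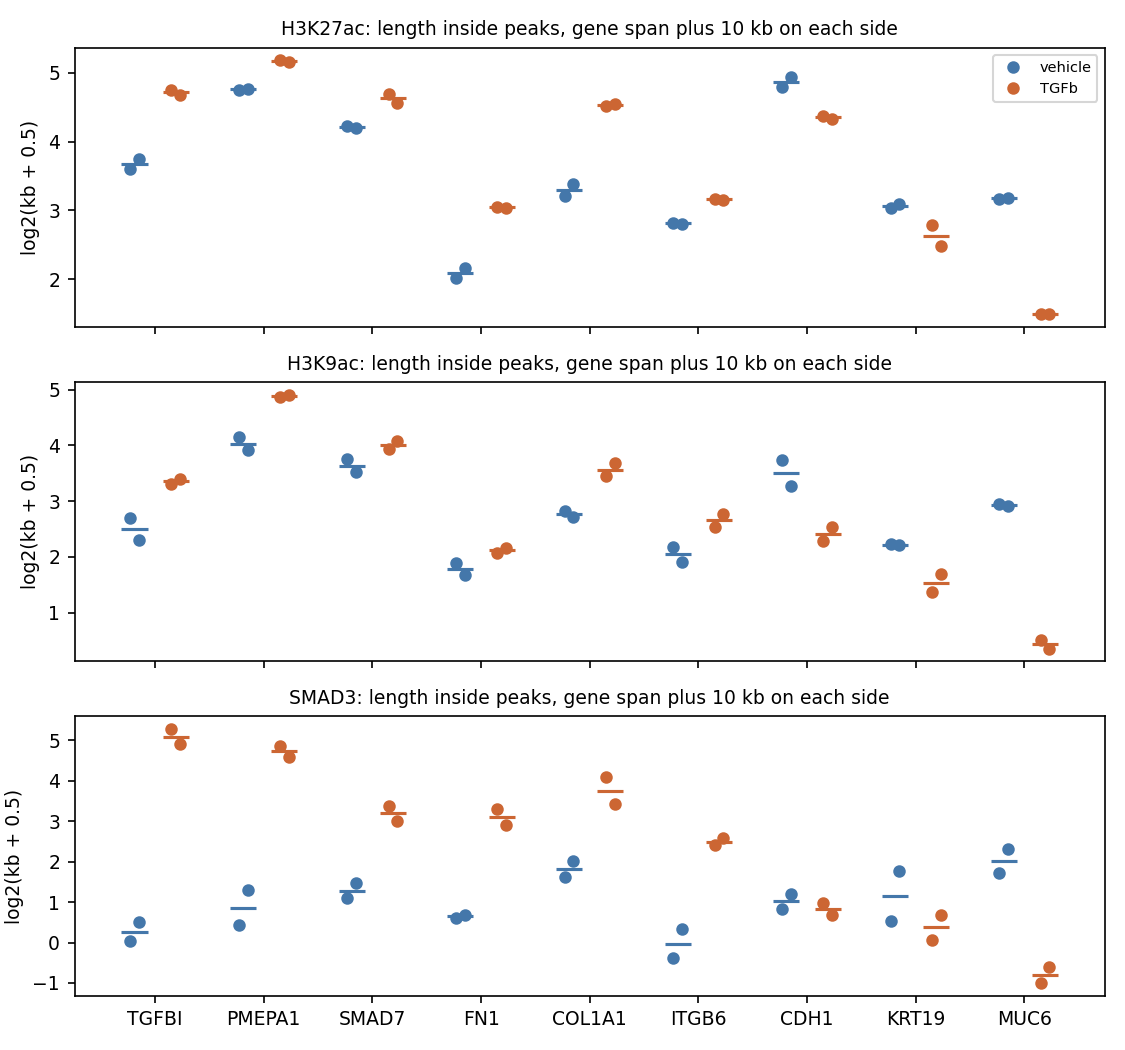
Length inside peaks in each gene with 10 kb on each side, as log2 of kb plus 0.5 and without centring (vertical axis), for 9 genes in each target, with points for libraries and short lines for the mean of 2 libraries. In SMAD3, TGFBI went from 0.720 to 33.8 kb and MUC6 from 3.66 to 0.0805 kb, while KRT19 and CDH1 were lower with TGF-beta in both marks.

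In H3K27ac, 12498 regions were specific to TGF-beta, 4931 to vehicle and 43717 constant, so 71.7% of treatment-specific regions were gains; mixed pairs of libraries gave 621 to 1320. Only 5.39% of gained and 8.40% of lost regions lay within 1 kb of a gene end, against 37.0% of constant regions (odds ratio of gained against constant 0.0970, 95% interval 0.0896 to 0.105, two-sided Fisher's exact test), and 41.2% of gained regions lay outside genes. Gained regions had a median length of 353 bp and constant regions 1035 bp. Comparing 1 vehicle with 1 TGF-beta library, regions gained per region lost were 2.15 and 1.61 within a sequencing lane, in pairs that share TGF-beta replicate 1, and 1.90 and 1.43 across lanes. Gained and lost regions numbered 23129 and 7059 without TGF-beta replicate 1, 24445 and 6426 without TGF-beta replicate 2, and 16213 and 12025 without vehicle replicate 2. Without vehicle replicate 1 they were close to even, at 14849 gained and 14207 lost. Leaving out a library widens the class that then rests on 1 library. These counts therefore cannot show whether the balance depends on a single library.

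By gene, 2067 of 13994 tested genes rose and 1631 fell in H3K27ac (limma with Benjamini-Hochberg adjustment), in 1595 and 1217 separate loci. The library median over genes covered in all 4 libraries moved by 0.09 on the log2 scale. Without centring 2507 rose and 880 fell, which took the share that rose from 55.9% to 74.0%. The total of 3698 became 6019 with a window of 50 kb and 2383 without TGF-beta replicate 2 (1448 up, 935 down), which is also the comparison within sequencing lane 7. Genes listed at 0 in both vehicle libraries and among the largest gains were SHISAL2A (5.49 and 6.73 kb in the TGF-beta libraries), BIRC7 (4.93 and 4.81 kb), an inhibitor of apoptosis, DMBX1 (4.77 and 4.55 kb), a homeobox gene, COMP (4.64 and 4.61 kb) and P4HA3 (4.20 and 4.61 kb), a collagen prolyl hydroxylase subunit. HAPLN3, a hyaluronan link protein, had 0.152 and 0 kb with vehicle and 6.27 and 5.82 kb with TGF-beta, and R3HDML 0.0240 and 0.0140 kb and 5.31 and 4.91 kb. Among the largest losses, ST6GALNAC1, a sialyltransferase of mucin-type glycans, GABRR2, BPIFB1, a secreted airway protein, and TMOD1, which caps actin filaments, were listed at 0 in both TGF-beta libraries and at 2.17 and 2.43 kb, 1.53 and 1.22 kb, 1.10 and 1.58 kb and 1.76 and 0.933 kb with vehicle. The others were APOB, ARHGEF38 (-2.32), GREB1 (-2.10) and BPIFA2 (-1.90).

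Of TGF-beta and SMAD targets, 15 of 29 measured members rose, 0 fell and 14 did not pass in H3K27ac. Adjusted over the list alone, 16 rose and 0 fell. The risers included TGFBI (0.95), ANGPTL4 (0.64), NEDD9 (0.60) and RUNX1 (0.55). The calls of SMAD7 (0.32) and PMEPA1 (0.33) were lost without vehicle replicate 2 or either TGF-beta library (adjusted p from 0.0616 to 0.143). SKIL and CCN2 had log2 changes of 0.27 and 0.19 that did not pass (adjusted p = 0.0552 and 0.105). Of matrix and collagen genes, 19 of 31 measured members rose, 3 fell and 9 did not pass (adjusted over the list alone, 22 rose and 3 fell), with ADAM12 (1.52) and COL4A1 (0.94) beside COL1A1 and FN1 among the risers. FBLN5 fell by 1.23. VCAN and COL12A1 fell by 0.31 and 0.29, calls lost without vehicle replicate 2 or either TGF-beta library for VCAN and when any 1 of the 4 was left out for COL12A1 (adjusted p from 0.0553 to 0.217). Of integrin and cytoskeleton genes, 9 of 25 measured members rose, 3 fell and 13 did not pass (adjusted over the list alone, 9 rose and 3 fell). TAGLN (1.14), FERMT2 (0.93), CALD1 (0.81) and PALLD (0.66) rose, and ACTA2, the smooth muscle actin of myofibroblasts, fell by 0.66. TPM2 fell by 0.49 and ITGB8 by 0.35. Both calls were lost without TGF-beta replicate 2, and that of ITGB8 also without TGF-beta replicate 1 (adjusted p from 0.0529 to 0.0757). ITGB6 rose by 0.26, a call lost when any 1 of the 4 libraries was left out (adjusted p from 0.0614 to 0.192).

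In camera with a preset correlation, TGF-beta targets (adjusted p = 2.58e-05) and matrix genes (2.57e-07) lay above other genes and interferon response genes below them (0.0345; 0.0733 with a window of 50 kb). The 3 calls were lost with adjusted p = 0.536, 0.394 and 0.536 with an estimated correlation, and the other 14 lists had adjusted p from 0.125 to 0.789. By region, gained H3K27ac regions outnumbered lost ones near TGF-beta targets by 123 to 9 (odds ratio against other genes 5.50, adjusted exact p = 1.14e-08, two-sided Fisher's test), near matrix genes by 125 to 15 (3.35, adjusted exact p = 3.65e-06) and near integrin and cytoskeleton genes by 70 to 10 (2.80, adjusted exact p = 0.00611). Near acetylation machinery genes 9 were gained and 12 lost (0.298, adjusted exact p = 0.0272).

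Of junction genes, 3 of 21 measured members rose, 5 fell and 13 did not pass in H3K27ac (adjusted over the list alone, 4 rose and 5 fell). ELF3 (-1.15), an epithelial transcription factor, fell with CDH1, and JUP (0.45), which encodes plakoglobin, rose. Of cholangiocyte identity genes, 5 of 19 measured members rose, 4 fell and 10 did not pass (adjusted over the list alone, 6 rose and 4 fell). SCTR (1.92), the secretin receptor, was among the risers, whereas PKHD1 (-1.26), which encodes fibrocystin, fell with KRT19. In windows around gene ends alone, JUP and SCTR had log2 changes of -0.084 and -0.062. KRT7 had a log2 change of -0.12 (adjusted p = 0.285). For genes of the epithelial to mesenchymal transition 6 of 15 measured members rose, 3 fell and 6 did not pass (adjusted over the list alone, 7 rose and 3 fell). SNAI1 (1.00) rose, WNT5B (-1.20) fell and SNAI2 had 0.14 (adjusted p = 0.306). Of secreted profibrogenic factors, 7 of 23 measured members rose, 4 fell and 12 did not pass (adjusted over the list alone, 8 rose and 4 fell), with PDGFA (1.09), IL11 (0.89), PDGFC (0.74) and CCL20 (0.62) among risers, CXCL1 (-0.82) and GDF15 (-0.73) among those that fell, and PDGFB at 0.07 (adjusted p = 0.591). Of BMP and ID targets, 3 of 12 measured members rose, 2 fell and 7 did not pass (adjusted over the list alone, 3 rose and 2 fell). NOG (1.56) rose and ATOH8 (-0.59) and BMP4 (-0.56) fell. For AP-1 and immediate early genes 3 of 19 measured members rose, 0 fell and 16 did not pass (adjusted over the list alone, 3 rose and 0 fell), FOSL2 (0.61), FOSB (0.58) and MAFK (0.44). For YAP targets 5 of 21 measured members rose, 0 fell and 16 did not pass (adjusted over the list alone, 5 rose and 1 fell), with AMOTL1 (0.72) and GADD45B (0.48).

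Of cell cycle genes, 1 of 25 measured members rose, 1 fell and 23 did not pass in H3K27ac (adjusted over the list alone, 1 rose and 1 fell). MCM5 (0.71), a replication licensing factor, rose, and AURKA fell by 0.45, a call lost without vehicle replicate 2 or TGF-beta replicate 2 (adjusted p from 0.0634 to 0.0918). Of acetylation machinery genes, 0 of 21 measured members rose, 4 fell and 17 did not pass (adjusted over the list alone, 0 rose and 4 fell), led by KAT2B (-0.90) and BRD3 (-0.50), a reader of acetylated histones. Of interferon response genes, 1 of 22 measured members rose, 5 fell and 16 did not pass (adjusted over the list alone, 1 rose and 5 fell). OAS2 (-0.59) was the largest loss and IRF7 (0.66) rose. Markers of other cells moved both ways: for hepatocytes 2 of 7 measured members rose, 4 fell and 1 did not pass (adjusted over the list alone, 2 rose and 4 fell), FGA (-1.55), FGB (-0.49) and TAT (-0.44) falling with APOB and APOA2 (1.23) and CYP3A4 (1.36) rising. For mesenchymal and endothelial markers 4 of 9 measured members rose, 1 fell and 4 did not pass (adjusted over the list alone, 5 rose and 1 fell), with THY1 (0.74) rising and NGFR (-0.72) falling. THY1 had -0.31 with a window of 50 kb. For leukocyte markers 2 of 11 measured members rose, 2 fell and 7 did not pass (adjusted over the list alone, 2 rose and 4 fell). CSF1R, which lies beside PDGFRB, rose from 0.543 ± 0.187 to 8.84 ± 0.299 kb, SPI1 rose by 1.03, and PTPRC (-0.83) and GNLY (-0.45) fell. Of housekeeping genes, 0 of 20 measured members rose, 2 fell and 18 did not pass (adjusted over the list alone, 0 rose and 0 fell). SDHA and YWHAZ fell by 0.35 and 0.29, calls lost without most single libraries (adjusted p from 0.0619 to 0.160; for SDHA all but vehicle replicate 2, for YWHAZ each of the 4). Among list members named for H3K27ac, the calls of VCAN, COL12A1, ITGB8, AURKA, SDHA and YWHAZ were lost without centring. Those of COL4A1, COL12A1, ACTA2, TPM2, CCL20, GADD45B, FGB, IRF7 and YWHAZ were lost with a window of 2.5 kb, those of CYP3A4, PTPRC and SPI1 with a window of 50 kb, and those of PMEPA1, VCAN, COL12A1, FERMT2, ITGB6 and PDGFC in windows around gene ends. Those of SMAD7, COL12A1, ITGB6 and CYP3A4 were lost with a pseudocount of 100 bp. Replicate number as a block lost that of ITGB6, and no filter those of COL12A1 and ITGB6. Medians were below 0 where tests pointed up for YAP targets (-0.03) and cholangiocyte genes (-0.01), and the mean for leukocyte markers was 0.22 where median and test were below 0.

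**Figure D4:**
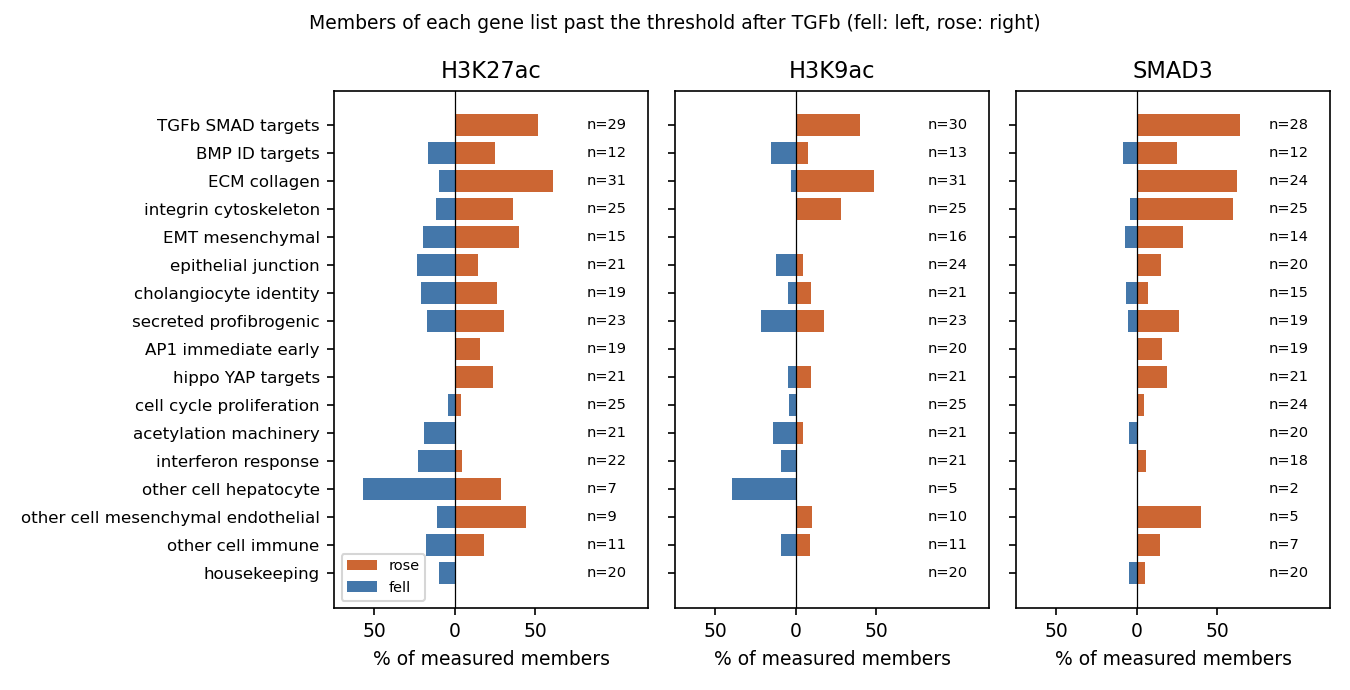
Percent of the measured members of each gene list (horizontal axis) that rose (right) or fell (left) past the threshold in each target, with the number measured (n) beside each bar. Matrix and collagen genes had 19 of 31 members up in H3K27ac, 15 of 31 in H3K9ac and 15 of 24 in SMAD3.

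The H3K9ac comparison asked the same of another acetylation mark. PMEPA1 rose from 15.9 ± 1.77 to 29.1 ± 0.668 kb (log2 change 0.95 ± 0.0804 SE, adjusted p = 0.000739), TGFBI rose from 5.20 ± 1.08 to 9.77 ± 0.441 kb (log2 change 0.95), and COL1A1 rose from 6.33 ± 0.370 to 11.4 ± 1.37 kb (0.89). MUC6 fell from 7.09 ± 0.121 to 0.850 ± 0.101 kb (log2 change -2.40 ± 0.104 SE, adjusted p = 3.67e-05), CDH1 fell from 11.0 ± 2.68 to 4.84 ± 0.686 kb (adjusted p = 0.00343), and KRT19 fell from 4.15 ± 0.0467 to 2.42 ± 0.450 kb (-0.59). AQP5, a water channel of secretory epithelia (chromosome 12, 49961872 to 49965682), fell from 3.78 ± 0.899 to 0.580 ± 0.136 kb (-1.89).

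Here gains did not outnumber losses: 3505 regions were specific to TGF-beta, 4188 to vehicle and 33894 constant, so 45.6% of treatment-specific regions were gains, and mixed pairs gave 170 to 1562. The direction of this balance turned with the same number of peaks per library (3778 gained, 3676 lost). Without TGF-beta replicate 1 there were 8389 gained and 4852 lost regions. Leaving out a library widens the class that then rests on 1 library, so such counts cannot show whether the balance depends on it. Gained regions numbered 6064 without vehicle replicate 1 and 5883 without TGF-beta replicate 2, and lost regions 8683 and 13806 without vehicle replicates 1 and 2 and 6667 without TGF-beta replicate 2. Regions gained per region lost were 0.348 and 0.764 between libraries of a sequencing lane, in pairs that share TGF-beta replicate 1, and 0.658 and 1.46 across lanes. Of gained regions 6.88% and of lost regions 12.4% lay within 1 kb of a gene end, against 50.9% of constant regions (odds ratio of gained against constant 0.0712, 95% interval 0.0625 to 0.0815, two-sided Fisher's exact test). Median lengths were 313, 315 and 1002 bp.

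By gene, 621 of 14605 tested genes rose and 762 fell in H3K9ac (limma with Benjamini-Hochberg adjustment), in 538 and 586 separate loci. The library median over genes covered in all 4 libraries moved by -0.09 on the log2 scale. Without centring 180 rose and 377 fell (557 in all), and the share that rose went from 44.9% to 32.3%. Among list members named with their lists, the calls lost without centring included those of SMAD7, FN1, COL4A2, PALLD, ITGB6, CALD1, SCTR, PDGFC, CSF2, IL11, BMP4, DLC1, GADD45B, CRIM1, E2F1, KAT8, HDAC9 and PDGFRB. With a window of 50 kb 2316 genes were called. Without TGF-beta replicate 1 the count was 899 and the balance turned (474 up, 425 down), as it did without vehicle replicate 1 (825 up, 721 down); within lane 7, without TGF-beta replicate 2, 455 rose and 755 fell. BIRC7, DMBX1, NKAIN4, LOC124904950, LOC124904930 and IFITM10 were listed at 0 in both vehicle libraries and at 3.03 and 3.74 kb, 2.15 and 1.96 kb, 2.51 and 3.47 kb, 1.98 and 2.33 kb, 3.65 and 4.09 kb and 1.81 and 2.01 kb in the TGF-beta libraries; BIRC7, NKAIN4 and LOC124904950 share windows on chromosome 20. KCNMA1, a calcium-activated potassium channel, went from 0.336 and 0 kb to 3.71 and 5.12 kb, and CGB5 rose by 2.38 on the log2 scale. The largest losses after MUC6 were CAPN9 (-2.23), a digestive tract calpain, TNFAIP2 (-2.01) and RIPOR3 (-1.99), AGT (-1.99), angiotensinogen, whose window overlaps that of CAPN9, INHBB (-1.92), an activin subunit that shares its values with LOC105373989, and AQP5.

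Of TGF-beta and SMAD targets, 12 of 30 measured members rose, 0 fell and 18 did not pass in H3K9ac (adjusted over the list alone, 15 rose and 0 fell). Beside PMEPA1 and TGFBI, ANGPTL4 (0.97), NEDD9 (0.66) and SMAD7 (0.47) rose. SKIL and CCN2 had log2 changes of 0.27 and 0.23 (adjusted p = 0.0695 and 0.101). Of matrix and collagen genes, 15 of 31 measured members rose, 1 fell and 15 did not pass (adjusted over the list alone, 18 rose and 2 fell). ADAM12 (0.92) and COL4A2 (0.58) rose, LAMA3 (-0.56) fell, and FN1 rose by 0.42, a call lost without TGF-beta replicate 1 (adjusted p = 0.0816). Of integrin and cytoskeleton genes, 7 of 25 measured members rose, 0 fell and 18 did not pass (adjusted over the list alone, 9 rose and 1 fell), with PALLD (0.78), TAGLN (0.72), ITGB6 (0.70) and CALD1 (0.68). In camera with a preset correlation these 3 lists lay above other genes (adjusted p = 2.32e-09, 8.57e-09 and 0.000446). With an estimated correlation, where 4 libraries leave few degrees of freedom, camera gave adjusted p = 0.311, 0.369 and 0.369. The other 14 lists had adjusted p from 0.229 to 0.840. Gained H3K9ac regions outnumbered lost ones by 47 to 16 near TGF-beta targets (odds ratio against other genes 3.83, adjusted exact p = 1.84e-05, two-sided Fisher's test), 33 to 13 near matrix genes (3.30, adjusted exact p = 0.00121) and 27 to 10 near integrin and cytoskeleton genes (3.50, adjusted exact p = 0.00211).

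Of junction genes, 1 of 24 measured members rose, 3 fell and 20 did not pass in H3K9ac (adjusted over the list alone, 3 rose and 5 fell). ELF3 (-1.34) and MAL2 (-0.72) fell with CDH1 and JUP (0.73) rose. Of cholangiocyte identity genes, 2 of 21 measured members rose, 1 fell and 18 did not pass (adjusted over the list alone, 2 rose and 3 fell), with SCTR (0.97) among the risers and KRT19 falling. KRT7 was at -0.29 (adjusted p = 0.0873) and SCTR at -0.036 in windows around gene ends alone. Of secreted factors, 4 of 23 measured members rose, 5 fell and 14 did not pass (adjusted over the list alone, 7 rose and 7 fell). PDGFC (0.79), CSF2 (0.75), CCL20 (0.72) and IL11 (0.68) rose, GDF15 (-1.13), a stress-induced cytokine, and EREG (-0.54) were among those that fell, and PDGFB had 0.06 (adjusted p = 0.699). For BMP and ID targets 1 of 13 measured members rose, 2 fell and 10 did not pass (adjusted over the list alone, 2 rose and 2 fell). NOG (0.73) rose, ATOH8 (-0.86) fell, and BMP4 fell by 0.31, a call lost when any 1 of the 4 libraries was left out (adjusted p from 0.0673 to 0.165). In limma 0 of 16 genes of the epithelial to mesenchymal transition passed, with 6 at an unadjusted p under 0.05 and 3 rose and 2 fell adjusted over the list alone; SNAI2 had 0.25 (adjusted p = 0.0791). It also called 0 of 20 AP-1 and immediate early genes (6 at an unadjusted p under 0.05; adjusted over the list alone, 0 rose and 0 fell) and 0 of 20 housekeeping genes (1 at an unadjusted p under 0.05; adjusted over the list alone, 0 rose and 0 fell).

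For YAP targets 2 of 21 measured members rose, 1 fell and 18 did not pass in H3K9ac (adjusted over the list alone, 2 rose and 1 fell). DLC1 (0.58) and GADD45B (0.40) rose and CRIM1 (-0.37) fell. Of cell cycle genes, 0 of 25 measured members rose, 1 fell and 24 did not pass (adjusted over the list alone, 0 rose and 0 fell), the loss being E2F1 (-0.34). Of acetylation machinery genes, 1 of 21 measured members rose, 3 fell and 17 did not pass (adjusted over the list alone, 1 rose and 3 fell). KAT2B (-0.52), BRD3 (-0.46) and KAT8 (-0.35) fell and HDAC9 (0.45) rose. For interferon response genes 0 of 21 measured members rose, 2 fell and 19 did not pass (adjusted over the list alone, 1 rose and 2 fell), OAS2 (-0.47) and ISG15 (-0.43). Of markers of other cells, for hepatocytes 0 of 5 measured members rose, 2 fell and 3 did not pass (adjusted over the list alone, 0 rose and 2 fell), APOB (-1.04) and TAT (-0.52). For mesenchymal and endothelial cells 1 of 10 measured members rose, 0 fell and 9 did not pass (adjusted over the list alone, 2 rose and 0 fell), PDGFRB (0.44); and for leukocytes 1 of 11 measured members rose, 1 fell and 9 did not pass (adjusted over the list alone, 1 rose and 1 fell), with CSF1R at 0 in both vehicle libraries and 1.28 and 1.66 kb after TGF-beta and GNLY (-1.03) falling. Without TGF-beta replicate 2 the calls of GADD45B, KAT2B, KAT8, HDAC9 and OAS2 were lost (adjusted p from 0.0546 to 0.124), without TGF-beta replicate 1 those of CRIM1, E2F1, KAT8 and PDGFRB (adjusted p from 0.0520 to 0.259), without vehicle replicate 1 those of GADD45B, E2F1 and KAT8, and without vehicle replicate 2 those of CRIM1 and E2F1. Among list members named for H3K9ac, calls lost with a window of 2.5 kb were those of CSF2, BMP4, GADD45B, E2F1, KAT8 and ISG15, with a window of 50 kb those of COL4A2, E2F1, KAT2B, KAT8 and OAS2, and in windows around gene ends those of COL4A2, LAMA3, JUP, PDGFC, EREG and CRIM1. A pseudocount of 100 bp lost those of CSF2, BMP4, GADD45B, CRIM1, E2F1 and KAT8, and the same number of peaks per library that of CRIM1. Tests and medians or means differed in sign for cholangiocyte genes (test and median down, mean 0.00), YAP targets (test up, median -0.02) and leukocyte markers (test and median down, mean 0.06).

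Whether TGF-beta changed H3K9ac and H3K27ac by different amounts was tested directly, as a treatment by mark term in limma over 8 libraries. The 8 were taken as independent. Libraries of both marks carry the same replicate numbers, and whether those of 1 number share chromatin is not given in the sources used here. SHISAL2A, listed at 0 with vehicle in H3K27ac, had 0.589 and 0.461 kb with vehicle and 0.762 and 1.24 kb with TGF-beta in H3K9ac (difference of log2 changes, H3K9ac minus H3K27ac, -3.00, adjusted p = 6.10e-05). HAPLN3 (-2.38), CREG2 (-2.33), P4HA3 (-2.29) and LHB (-2.19), a gonadotropin subunit beside CGB7, also had lower changes in H3K9ac. Higher values in H3K9ac were found for SGCE (1.52), an adhesion-associated sarcoglycan, TMOD1 (1.41), TMC5 (1.38), NRG2 (1.35), a growth factor, and APOB (1.34), each of which fell in H3K27ac. Without single libraries the calls of TMC5 (H3K9ac vehicle replicate 1 and TGF-beta replicate 2 of either mark) and TMOD1 (H3K9ac vehicle replicate 2 and both H3K9ac TGF-beta libraries) were lost (adjusted p from 0.0506 to 0.0645), as both were with a window of 50 kb.

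The change differed between the marks for 1027 of 13600 genes, 262 with a higher and 765 with a lower value in H3K9ac, in 238 and 641 separate loci. Of the 765, 681 (89.0%) rose in H3K27ac, with a median log2 change of 0.78 there and 0.09 in H3K9ac, and 133 passed in both marks with the same sign. Of the 262, 222 (84.7%) fell in H3K27ac, with medians of -0.69 and -0.05. These genes were picked by the same changes, so the medians describe the sets and are not a separate test of how the marks differ. Among genes named above, the difference was 0.62 for PMEPA1 (adjusted p = 0.00767), -0.45 for FN1 (0.0272) and 0.44 for ITGB6 (0.0494), and for TGFBI, COL1A1, CDH1 and KRT19 it did not pass (adjusted p = 0.986, 0.200, 0.180 and 0.848). None of the 17 lists passed in camera on this term; matrix genes had the lowest p (0.0121, adjusted p = 0.205; median difference -0.14). Within lane 7, 261 genes were called (50 higher, 211 lower), 235 of them among the 1027. The count was 679 without H3K9ac vehicle replicate 1, 511 and 679 without H3K9ac TGF-beta replicates 1 and 2, 659 and 583 without H3K27ac TGF-beta replicates 1 and 2, and 1649 with a window of 50 kb. Without centring, which moved the median difference from 0.02 to -0.16, 1139 genes passed, 65 with a higher and 1074 with a lower value in H3K9ac, so the 262 depended on centring.

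**Figure D5:**
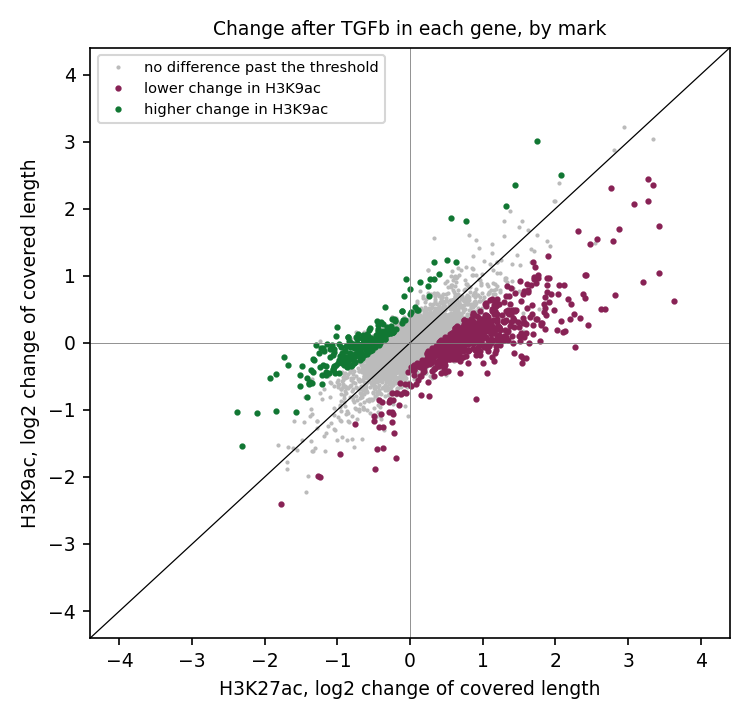
Change in covered length after TGF-beta for each gene, as log2 change in H3K27ac (horizontal axis) and H3K9ac (vertical axis), with the line of equal change. Coloured points are the 1027 genes whose change differed between the marks, 765 lower and 262 higher in H3K9ac.

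The last comparison asked how SMAD3 gains and acetylation changes lay relative to each other. The vehicle libraries of each target are separate libraries, but H3K9ac and H3K27ac libraries of the same number may share chromatin, which could add to their overlap. Of the 3505 H3K9ac regions gained after TGF-beta, 633 (18.1%) overlapped a gained H3K27ac region, against 19 of 4188 lost H3K9ac regions (0.454%) and 626 of 33894 constant regions (1.85%), with odds ratios of 48.4 (95% interval 30.0 to 74.2) and 11.7 (10.4 to 13.2). Lost H3K9ac regions overlapped lost H3K27ac regions in 296 cases (7.07%), and gained H3K9ac regions overlapped lost H3K27ac regions in 0. Of the 5253 gained SMAD3 regions, 60.5% lay on constant H3K27ac regions, 5.24% on gained H3K27ac regions and 71.9% on any H3K27ac region. For H3K9ac the shares were 58.2%, 6.55% and 71.9%. Constant SMAD3 regions lay on H3K27ac in 96.4% and on H3K9ac in 97.1% of cases.

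Seen from the acetylated regions, a gained SMAD3 region touched 2.38% of gained, 0.385% of lost and 5.96% of constant H3K27ac regions (gained against constant, odds ratio 0.384, 95% interval 0.340 to 0.434; gained against lost, 6.29, 3.88 to 9.72). For H3K9ac the shares were 10.3%, 0.669% and 8.29% (gained against lost, 17.0, 11.4 to 24.6). The excess over constant H3K9ac regions, an odds ratio of 1.27 (1.13 to 1.42, exact p = 8.85e-05, two-sided Fisher's test), was 1.12 (exact p = 0.0710) when an overlap had to span at least 0.5 of the shorter region and 1.08 (exact p = 0.362) with the same number of peaks per library. With region centres of 200 bp it was 1.87 (8.70% against 4.84%, 1.65 to 2.13, exact p = 1.21e-19), so the excess depended on the setting. The lower share of gained than of constant H3K27ac regions was less marked with region centres (odds ratio 0.722, 0.623 to 0.841), where the greater length of constant regions does not count. For gained H3K9ac regions on gained H3K27ac regions, centres gave 21.7 in place of 11.7. With the same number of peaks the odds ratios against lost regions, 6.29 and 17.0, were 13.9 and 37.7. Regions within a library are not independent replicates.

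Genes that changed in 1 target tended to change in the others. H3K27ac and H3K9ac shared 470 genes that rose, where 80.2 were expected for independent sets (odds ratio 36.9, 95% interval 29.5 to 46.4), and 442 that fell (expected 78.5; 18.9, 16.0 to 22.5). SMAD3 and H3K27ac shared 461 risers (expected 173; 4.58, 4.02 to 5.22), COL1A1 and FN1 among them, and 88 genes that fell (expected 21.3; 6.90, 5.13 to 9.24). SMAD3 and H3K9ac shared 268 risers (expected 51.3; 13.3, 10.9 to 16.3), TGFBI among them, and 59 genes that fell (expected 8.75; 10.0, 7.18 to 13.8). In the same order, the shared risers lay in 407, 358 and 225 separate loci and the shared fallers in 357, 72 and 51, and the tests take genes as independent. The sizes depended on the setting. Without centring the shared risers were 163, 653 and 107 (odds ratios 211, 4.08 and 35.3), and the shared fallers 214, 7 and 6 (37.1, 44.9 and 82.8). The same number of peaks per library gave 525, 250 and 199 risers (37.3, 5.89 and 17.0) and 453, 45 and 38 fallers (19.6, 9.70 and 19.1), and a window of 50 kb 869, 863 and 564 risers (25.2, 4.11 and 10.2) and 841, 312 and 171 fallers (16.7, 3.45 and 4.84). Across genes, which are not independent replicates, log2 changes correlated at r = 0.645 and rho = 0.532 for the 2 marks, 0.363 and 0.244 for SMAD3 with H3K27ac, and 0.368 and 0.165 for SMAD3 with H3K9ac.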

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

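The tests of peak number and of sequencing lane, and the lane test of the difference between the marks, were chosen only after the results they bear on were seen; the test of low H3K9ac signal was planned.

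A difference in the TGF-beta response between H3K9ac and H3K27ac was the reason each of the following was singled out, by the treatment by mark term in limma. It passed for 1027 genes. The largest differences, H3K9ac minus H3K27ac on the log2 scale, were -3.00 for SHISAL2A, -2.38 for HAPLN3, -2.33 for CREG2, -2.29 for P4HA3 and -2.19 for LHB, and 1.52 for SGCE, 1.41 for TMOD1, 1.38 for TMC5, 1.35 for NRG2 and 1.34 for APOB. SHISAL2A and P4HA3 with vehicle and TMOD1 with TGF-beta were listed at 0 in H3K27ac, so the sizes given for them depend on the pseudocount.

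Most of these genes changed less in H3K9ac than in H3K27ac. Too little H3K9ac at these genes would put their vehicle level among the lowest. Genes that rose in H3K27ac with a lower change in H3K9ac had a median of 2.39 kb of H3K9ac with vehicle (bootstrap 95% interval 2.29 to 2.55). That lay above the 25th percentile of tested genes (2.08 kb) and below their median (3.14 kb). In H3K27ac the same genes started from a median of 1.97 kb, against 2.94 kb for all tested genes. Genes that fell in H3K27ac with a higher change in H3K9ac started from 3.20 kb there. Whether the difference between the marks depends on the starting level in H3K27ac was not tested. The lane of TGF-beta replicate 2 stays open as a cause. Without the lane 8 libraries of both marks 211 genes were still lower and 50 higher. That fit leaves each mark only TGF-beta replicate 1, assumed to vary like the vehicle libraries. It cannot tell a response to TGF-beta from a difference of that single library, so it does not settle the lane. A difference between the marks in how they respond stays open, as do differences in antibody yield and read depth, which peak lists do not show.

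H3K27ac had more gained than lost regions. With the same number of peaks per library, gains over all 4 libraries still exceeded losses by 4302 regions, and the highest mixed pair held 1084 regions. Single pairs then gave 1.45 and 1.14 regions gained per region lost with TGF-beta replicate 1, and 1.42 and 1.12 with replicate 2. Libraries of 1 treatment differed from each other by ratios of 1.42 (vehicle) and 1.03 (TGF-beta). A larger number of peaks after TGF-beta is therefore not settled as a cause. The sequencing lane stays open. Pairs of 1 vehicle and 1 TGF-beta library within lane 7 gave at least 1.61 regions gained per region lost, but they share TGF-beta replicate 1, and the vehicle libraries differed from each other by a ratio of 1.53. A response of the cells to TGF-beta also stays open as a hypothesis, beside read depth and antibody yield, which were not tested.

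H3K9ac had more lost than gained regions. The number of peaks in vehicle replicate 1 may account for the excess over all 4 libraries, since with the same number of peaks per library losses minus gains came to -102 regions. Single pairs do not settle it: with the same number of peaks, regions gained per region lost were 0.550 and 0.783 with TGF-beta replicate 1 and 0.909 and 1.29 with TGF-beta replicate 2, and libraries of 1 treatment differed from each other by ratios of 1.60 and 2.46. The sequencing lane stays open as well. Within lane 7 the highest ratio of regions gained to lost was 0.764, but both pairs share TGF-beta replicate 1, and the vehicle libraries differed from each other by a ratio of 2.89. A response of the cells to TGF-beta and a difference of TGF-beta replicate 1 from the other libraries stay open.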

How the results depend on the processing

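The leave-one-out fits of the treatment by mark test, the windows around both gene ends, the crossed block, the fit without both lane 8 libraries and the location test with the same number of peaks were chosen only after the results were seen.

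For the counts and tests that answer the comparisons, 22 results had 142 alternatives, of which 92 stayed within 1.5 times the value or on the same side of the threshold and 50 changed. Gained and lost regions numbered 5212 and 1926 in H3K27ac, 1611 and 1891 in H3K9ac and 3056 and 150 in SMAD3 when peaks within 500 bp were merged, and 5958 and 2144, 1107 and 1553, and 3004 and 6 with the better-scored 0.5 of peaks; both settings leave fewer regions. With the same number of peaks per library SMAD3 gave 1691 gained and 563 lost regions, and 712 genes in place of 1605. Without single libraries, gained regions ranged from 14849 to 24445 in H3K27ac, 4178 to 8389 in H3K9ac and 5504 to 12572 in SMAD3, and lost regions from 6426 to 14207, 4852 to 13806 and 406 to 1627; a class defined by fewer libraries is wider by construction. A left-out library leaves a group of 1, assumed to vary like the other group: genes called then ranged from 2383 to 3230 in H3K27ac, 899 to 1546 in H3K9ac and 789 to 1814 in SMAD3, and from 511 to 973 for the treatment by mark test. A window of 50 kb gave 6019, 2316 and 3021 genes and 1649 for that test, no centring 557 genes in H3K9ac, and the fit without both lane 8 libraries 261; the cause was not tested. Camera called 3 lists per target with a preset and 0 with an estimated correlation, where 4 libraries leave too few degrees of freedom to judge the correlation. With a window of 50 kb, AP-1 genes passed in camera in SMAD3 (adjusted p = 0.0467) and interferon genes did not in H3K27ac (adjusted p = 0.0733). The odds ratio of gained SMAD3 regions on gained against constant H3K9ac regions was 1.12 with overlaps of 0.5 of the shorter region and 1.08 with the same number of peaks, but 1.87 with region centres of 200 bp. Replicate numbers are not known to pair libraries, and with replicate number as a block 3666 genes were called in H3K27ac (2065 up, 1601 down), 1706 in H3K9ac (753, 953), 1671 in SMAD3 (1471, 200) and 762 for the treatment by mark test. Residuals of libraries with the same number correlated at -0.0163, -0.136 and -0.0689 across genes. With 2 libraries per group, crossed numbers give the same values with the other sign, so pairing was neither shown nor excluded. With the numbers crossed in H3K9ac 1360 genes were called (622, 738), against 1706 with equal numbers. Log2 changes of named genes reversed in windows around gene ends alone (JUP -0.084 and SCTR -0.062 in H3K27ac, SCTR -0.036 in H3K9ac), with a window of 50 kb (THY1 -0.31 and SLC4A2 0.22 in H3K27ac, THY1 -0.86 in H3K9ac, MOK -0.010 in SMAD3) and with a window of 2.5 kb (CGN -0.10 and IER3 -0.067 in SMAD3); the cause was not tested, but wider windows take in neighbouring genes and the others leave out part of the gene. Among called genes named in the text, of the 118, 88 and 85 in H3K27ac, H3K9ac and SMAD3, 84, 50 and 45 kept their call and direction under every alternative in which they were tested. Some genes were not tested under some alternatives. The planned search for sequence motifs at SMAD3 regions and its alternatives were not run, since no genome sequence was used. Read depth sets how many peaks are found and is not known, so a gene or region listed at 0 is not shown to lack the mark.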

Other observations

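The tests of region length in the form given and the windows around gene ends were chosen only after related results were seen, the test of distance to SMAD3 regions was planned, and the genes named here were chosen after their values were seen.

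Of 12313 genes tested in all 3 targets, 226 were higher after TGF-beta in every target and 45 were lower, in 189 and 37 separate loci; without centring the counts were 103 and 6, with the same number of peaks per library 158 and 32, and with a window of 50 kb 467 and 155. The higher set was led by BIRC7, COMP, LOC124904930, R3HDML, NKAIN4 and XKR7, which was listed at 0 with vehicle and had 3.17 and 3.09 kb in H3K27ac, 1.75 and 1.91 kb in H3K9ac and 2.97 and 1.86 kb in SMAD3 after TGF-beta. All but COMP lie on chromosome 20, where BIRC7 and NKAIN4 share windows. The lower set held MUC6 (log2 changes -1.77 in H3K27ac, -2.40 in H3K9ac and -3.15 in SMAD3), GREB1, TNFAIP2 (-1.23, -2.01 and -0.89), ACSS1, the acetyltransferase gene KAT2B, BMP4, and the epithelial genes KRT15 (-0.81, -0.52 and -1.10), KRT19 and TJP3 (-0.69, -0.56 and -0.58), a tight junction protein. KRT15 and KRT19 have the same SMAD3 values and so are not separate losses there. In SMAD3 the calls of KRT15 and KRT19 were lost without vehicle replicate 5, that of TJP3 without vehicle replicate 4, that of KAT2B without either replicate 4 library and that of BMP4 when any 1 of the 4 was left out (adjusted p from 0.0697 to 0.154). In H3K9ac those of KRT15 and TJP3 were lost without TGF-beta replicate 1, that of KAT2B without TGF-beta replicate 2 and that of BMP4 when any 1 library was left out (adjusted p from 0.0553 to 0.165). Without centring the SMAD3 calls of TNFAIP2, KAT2B, BMP4, KRT15, KRT19 and TJP3 were lost, as were the H3K9ac calls of BMP4, KRT15 and TJP3. The same number of peaks per library ended the SMAD3 calls of KAT2B, BMP4, KRT15, KRT19 and TJP3. A window of 50 kb ended those of KRT15, KRT19 and TJP3. The H3K9ac calls of ACSS1 in windows around gene ends and of KAT2B with a window of 50 kb were lost as well. Over the alternatives tried, the SMAD3 call was lost 10 times for KRT19, 9 for KRT15 and 10 for BMP4.

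Genes with higher SMAD3 and lower acetylation were fewer than independent sets would give. SMAD3 was higher where H3K27ac was lower in 41 genes (expected 139; odds ratio 0.248, exact p = 4.44e-26, two-sided Fisher's test), where H3K9ac was lower in 28 (expected 57.5; odds ratio 0.447, exact p = 6.00e-06), and where both were lower in 10. Among the 10 were KCNIP3 (-0.95 in H3K27ac, -0.87 in H3K9ac and 0.60 in SMAD3), SLC48A1 (-0.79, -0.69 and 0.72), MOK (-0.81, -0.41 and 0.70) and CDC42BPG (-0.79, -0.53 and 0.74). The SMAD3 calls were lost without vehicle replicate 4 for KCNIP3, SLC48A1 and MOK and without vehicle replicate 5 for KCNIP3 (adjusted p from 0.0504 to 0.0991), and the H3K9ac call of MOK was lost without TGF-beta replicate 2 (adjusted p = 0.0610). With a window of 50 kb MOK had -0.010 in SMAD3, and the SMAD3 calls of KCNIP3, SLC48A1 and CDC42BPG were lost. Without centring the H3K9ac calls of MOK and CDC42BPG were lost. With the same number of peaks per library the SMAD3 calls of SLC48A1 and CDC42BPG were lost, as was that of KCNIP3 with a pseudocount of 2000 bp and the H3K9ac call of MOK in windows around gene ends. The counts of 41 and 28 were 17 and 8 with the same number of peaks, 31 and 11 without centring and 104 and 37 with a window of 50 kb. The 41 genes lie in 36 separate loci, and the tests take genes as independent.

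In constant acetylated regions, those touched by a gained SMAD3 region may have become longer after TGF-beta than others of the same length with vehicle. A region counted as touched if the SMAD3 region overlapped sequence inside peaks of both vehicle libraries, so that growth after TGF-beta could not decide it. In H3K27ac, 2488 touched regions had a median log2 ratio of length 0.24 above that of 41229 other regions in the same 10 classes of vehicle length, and 0.23 to 0.26 above it in 4 of 4 pairs of 1 vehicle and 1 TGF-beta library. Between the vehicle libraries the difference was -0.0012 and 0.015. In H3K9ac, with 2704 touched and 31190 other regions, it was 0.20, and 0.17 to 0.23 in 4 of 4 pairs, against -0.029 and 0.043 between the vehicle libraries. Regions touched by a constant SMAD3 region differed from others by -0.039 to 0.0020 in H3K27ac and by 0.0096 to 0.16 in H3K9ac, so in H3K9ac part of the difference may not be particular to gained SMAD3 regions. The permutation p, 0.001 in both marks, was the smallest that 1000 permutations can give, and it takes regions, not libraries, as units.

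A further hypothesis is that H3K27ac gains away from gene ends lie near SMAD3 gains without touching them. A gained SMAD3 region lay within 10 kb, without contact, of 16.9% of gained, 12.1% of constant and 6.79% of lost H3K27ac regions (odds ratios 1.48 and 2.79, two-sided Fisher's exact test). The shares for H3K9ac were 30.4%, 18.3% and 11.0% (odds ratios 1.96 and 3.52). The excess is consistent with acetylation gained beside SMAD3 sites, but genes with many peaks would give it as well, and that was not tested.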
